A study of Rattus norvegicus with 20 samples.

How the data were processed

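Placental tissue of Wistar rats was collected on gestational day 14 from dams that had eaten a treat carrying either a vehicle or a mixture of organophosphate flame retardants (OPFR, chemicals added to foams and plastics to slow burning) daily from day 1 to day 14. The samples used here came from the 8 mg/kg OPFR group and the vehicle group. Per the labels' protocols, the fetal side of the placenta was separated from the maternal side, the frozen tissue was cryosectioned, and 1 punch through the junctional and labyrinth zones was used for RNA. The labels give 20 libraries: 5 from females and 5 from males in each treatment. A sample protocol in the labels counts 4 vehicle samples per sex, whereas the series text and the sample list give 5, and 5 were used.

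Per the labels' protocols, poly(A) RNA was made into libraries with a directional kit, which marks the strand, and sequenced as single-end reads on 1 Illumina lane. The submitters' processing notes name FastQC, STAR, HTSeq and DESeq2 and the rat genome build rn6, without versions or order. The annotation release and the strand setting of the counting are not given in the sources used here, so values of overlapping genes, antisense genes and near-identical copies are uncertain where the counting could split or mix them. The deposited table holds raw read counts per gene, as whole numbers, for 32402 Ensembl rat gene IDs. Its sheet name calls the values normalized, but the columns hold whole numbers with different totals, and they were treated as counts. No sample column was left unused (0 columns). The files do not pair the IDs with gene names. A RefSeq table of 47357 rat genes was searched for the IDs. It gave an Ensembl ID for 0 of its genes, so no match was possible and 0 matched. The 27 lists of pathway and cell type genes planned for this tissue were therefore not analysed here, nor were the planned covariates for tissue makeup. IDs are printed as given, without coordinates.

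Totals ranged from 17458483 to 67125069 counts per library. Genes with enough counts for the 4 groups were kept with edgeR's filterByExpr, which left 14463 of the 21462 genes with any read and 99.95% of the reads. Library sizes were scaled with TMM factors, and CPM values, counts scaled to a library size of 1000000, were computed with them. Libraries of 1 group were compared in 40 pairs by a chi-square statistic over genes, which lay between 29.7 and 623.8 per degree of freedom, so no pair matched within sampling noise.

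The main test was edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3) with a robust fit to all 20 libraries, two-sided, with Benjamini-Hochberg adjustment over the 14463 genes and a threshold of 0.05 for the adjusted p. Treatment over both sexes and female against male came from a model with treatment and sex as terms. Treatment within females, treatment within males and their difference came from a model of the 4 groups. Log2 fold changes are OPFR over vehicle or female over male. In the text, a called gene is one with an adjusted p under the threshold. The labels give each library a number before a decimal point that it shares with at least 1 other library, without saying what this label number marks. The 10 OPFR libraries carry 5 numbers, each on replicates that follow one another (1 and 2 to 9 and 10, 1 of each sex). The 10 vehicle libraries carry 4, on replicates 1 and 2, 3 and 4, 5 to 8, and 9 and 10, and within a treatment replicate numbers run on over both sexes. If a number marks a litter, libraries that share it are not independent, and the p-values then measure in part the spread between related samples. The library indices in the labels run in 1 block for each treatment, so any effect of library order cannot be separated from treatment.

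Counts for the 14463 genes were simulated with the real means, dispersions and library sizes, with 200 genes changed by known folds, and the test was run on them. The libraries were simulated as independent, so these shares and false calls leave out any structure shared by libraries, such as that of a label number. For OPFR against vehicle over both sexes it recovered 10% of the genes changed 1.25-fold, 56% of those changed 1.5-fold, 78% of those changed 2-fold and 94% of those changed 4-fold, with 1 false call among 120 calls. The corresponding shares were 2%, 32%, 62% and 86% within females and 0%, 20%, 66% and 88% within males. For the interaction they were 0%, 10%, 36% and 78%, and for female against male 8%, 48%, 82% and 96%.

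The rule for named genes, set before the data were examined, took up to 10 called genes in each direction with a mean normalized count of at least 50, or the 5 with the smallest p where none was called, and members of the lists. With no names for the IDs, it was reduced to 2 IDs in each direction for treatment (smallest p) and 2 for sex (largest fold change). Alternatives set before the data were examined were DESeq2 1.42.0, limma 3.58.1 with voom weights, DESeq2 size factors or upper quartile scaling within edgeR, no filter on low counts, a mean normalized count of at least 50, each library left out in turn, the replicate number as a block, label numbers as correlated groups or as a block, counts summed by label number, 1 library per sex of the label number that 4 vehicle libraries share, a term for low against high label numbers, 1 surrogate variable (sva 3.50.0), and each sex fitted alone. Added after seeing the data were the library labelled OPFR male replicate 7 entered as female, the omission of the libraries labelled OPFR male replicates 5 and 7 with edgeR and with DESeq2, and 3 surrogate variables.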

Results

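RNA from the fetal side of the rat placenta was sequenced in 20 libraries that crossed maternal OPFR exposure (8 mg/kg against vehicle) with fetal sex, with 5 libraries in each of the 4 groups. Total counts averaged 36522793 ± 17653402 (SD, n = 5) in OPFR females, 28105122 ± 4932370 (n = 5) in OPFR males, 21007447 ± 3852730 (n = 5) in vehicle females and 24598620 ± 3919305 (n = 5) in vehicle males. The OPFR libraries were deeper than the vehicle libraries, at 32313958 ± 13000113 against 22803034 ± 4123904 counts (SD, n = 10 each, two-sided permutation test on log2 totals with 100000 resamples, p = 0.00659). The first principal component of log2 CPM held 35.7% of the variance and the second 13.6%, and libraries of both treatments and both sexes lay on either side of each.

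**Figure D1:**
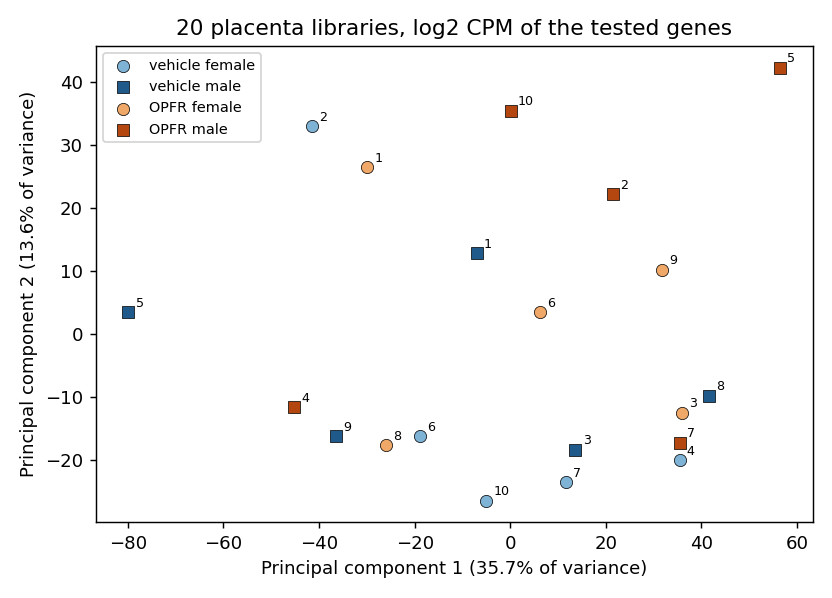
Principal components 1 and 2 of log2 CPM for the 20 libraries, with 1 point per library, coloured by group and marked with its replicate number within its treatment. Vehicle male replicate 5 lay lowest on component 1 at -79.91, and OPFR male replicate 5 highest at 56.43.

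Whether maternal OPFR exposure changed the placental transcriptome was first asked over both sexes. Among genes with a mean normalized count of at least 50, the smallest p was that of ENSRNOG00000014171. It averaged 3.01 ± 0.63 CPM in OPFR libraries and 38.6 ± 35.5 CPM in vehicle libraries (SD, n = 10 each). Its log2 fold change was -3.67 ± 0.64 (SE), with an adjusted p of 0.111 in edgeR's quasi-likelihood test, so it was not called. Its vehicle values followed the label number, a number in the descriptions that libraries share: they lay between 35.7 and 97.9 CPM in replicates 5 to 8, which share 1 number, between 39.9 and 79.1 in replicates 9 and 10, between 2.33 and 2.92 in replicates 1 and 2 and between 3.54 and 4.38 in replicates 3 and 4. The OPFR libraries ranged from 1.86 to 4.2 CPM.

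**Figure D2:**
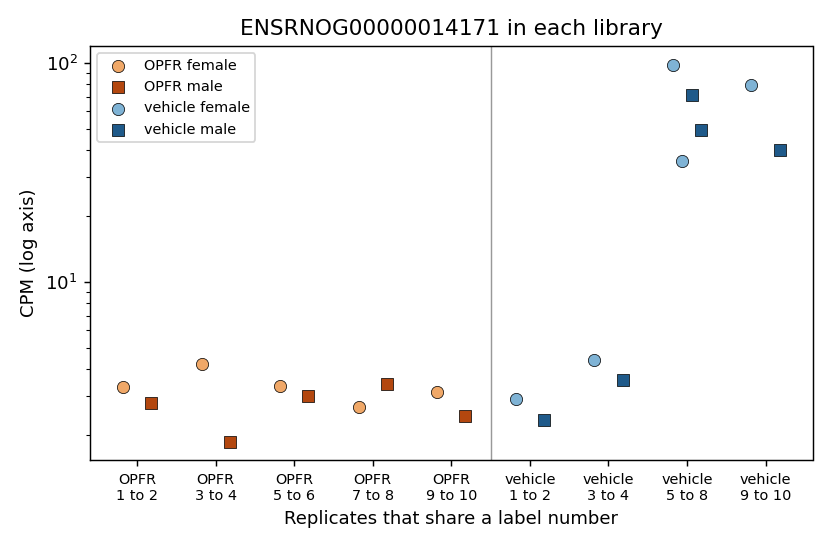
CPM of ENSRNOG00000014171 on a log axis in each of the 20 libraries, set out by shared label number, with OPFR left of the line and vehicle right of it. Vehicle replicates 5 to 10 lie between 35.7 and 97.9 CPM and the other 14 libraries between 1.86 and 4.38.

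The other 3 genes printed for treatment under the reduced rule differed less in size and more evenly across libraries. ENSRNOG00000020683 averaged 177 ± 8.88 CPM in OPFR and 149 ± 11.4 CPM in vehicle libraries (SD, n = 10 each), a log2 fold change of 0.25 ± 0.05 (SE). ENSRNOG00000014530 averaged 68.9 ± 7.06 against 55.0 ± 6.89 CPM, a log2 fold change of 0.32 ± 0.06. ENSRNOG00000002899 averaged 56.3 ± 5.04 against 68.4 ± 4.31 CPM, a log2 fold change of -0.28 ± 0.06. None of these 3 genes was called, each with an adjusted p of 0.111 in edgeR.

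Across the 14463 genes tested over both sexes, edgeR called 0. At an unadjusted p under 0.05 there were 1866 genes, 1140 higher and 726 lower in OPFR, where 723 would be reached with no differences at all. Their median log2 change was 0.267 in size, and 91 of them differed by more than 2-fold. The standard error of the log2 fold change had a median of 0.129. DESeq2 called 187 genes on the same counts, 113 higher and 74 lower, with a median fold of 1.24, and 12 of them differed by more than 2-fold. All 187 had the same direction and an unadjusted p under 0.05 in edgeR. With limma-voom 0 were called. Without vehicle male replicate 3, edgeR called 27 genes, 23 higher and 4 lower. The description of that library, alone among those used, sets its sample number against another with the word "not", which the labels do not explain. Whether this bears on the count was not tested.

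**Figure D3:**
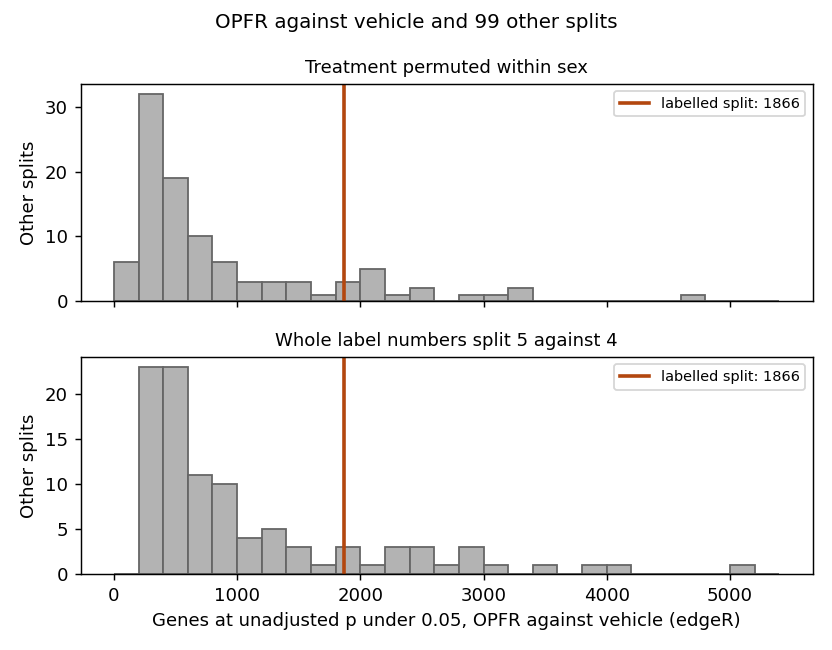
Number of genes at an unadjusted p under 0.05 in edgeR for OPFR against vehicle over both sexes, with the labelled split as a line and 99 other splits as bars, for treatment permuted within sex (top) and for whole label numbers split 5 against 4 (bottom). The labelled split gave 1866 genes, and the highest of the others gave 4680 (top) and 5021 (bottom).

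Within females, edgeR called 0 genes for OPFR against vehicle (5 libraries each), 591 genes had an unadjusted p under 0.05 (346 higher, 245 lower), DESeq2 called 1 and limma-voom 0. Without OPFR female replicate 9, edgeR called 1 gene. The count at an unadjusted p under 0.05 in females moved to 1215 without vehicle female replicate 2 and to 389 without vehicle female replicate 10. Within males, edgeR called 0 genes, 1233 had an unadjusted p under 0.05 (781 higher, 452 lower), and the smallest adjusted p was 0.157. DESeq2 called 8 genes in males, 4 in each direction, and limma-voom 0. Without vehicle male replicate 9, edgeR called 1 gene. The count at an unadjusted p under 0.05 in males moved to 2365 without OPFR male replicate 4, to 753 without OPFR male replicate 2 and to 785 without vehicle male replicate 9. Of the genes at an unadjusted p under 0.05, 216 in males and 68 in females differed by more than 2-fold.

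The difference between the female and male responses was tested directly. edgeR called 0 genes for the treatment by sex interaction, with 190 at an unadjusted p under 0.05 against 723 reached with no differences, and DESeq2 and limma-voom each called 0. The count of 190 moved to 454 without OPFR male replicate 4 and to 392 without vehicle female replicate 2. Across the 14463 genes, which are not independent replicates, the log2 fold changes of females and males had a Pearson correlation of 0.304 and a Spearman correlation of 0.423. There were 195 genes with an unadjusted p under 0.05 in both sexes, where independent lists would share 50.4, and all 195 had the same direction. This overlap was not counted in other splits of the libraries. Counting the labelled split, a Pearson correlation as high was given by 11 of 100 splits of treatment within sex. For whole label numbers it was 16 of 100 splits, counted alike, so chance is not excluded for the correlation. The vehicle libraries of the 2 sexes are different libraries, but they share label numbers.

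1 library weighed on the male values. In the library labelled OPFR male replicate 5, 92 genes had at least 5 CPM and over 10 times the level of every other library, and summed to 24378 CPM and held 2.61% of its reads. The same genes summed to 566 CPM in OPFR male replicate 10 and to at most 153 CPM in each of the other 18 libraries. No other library had more than 2 such genes. The 39 of these genes that were abundant enough to be tested were among the 216 genes beyond 2-fold at an unadjusted p under 0.05 in males, and 28 were among the 122 of the interaction. Without this library, 667 genes had an unadjusted p under 0.05 in males in place of 1233. The 39 tested genes alone are too few to account for that drop. Other libraries moved the count too: 753 without OPFR male replicate 2, and 785 and 828 without vehicle male replicates 9 and 5. It rose to 2365 without OPFR male replicate 4.

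**Figure D4:**
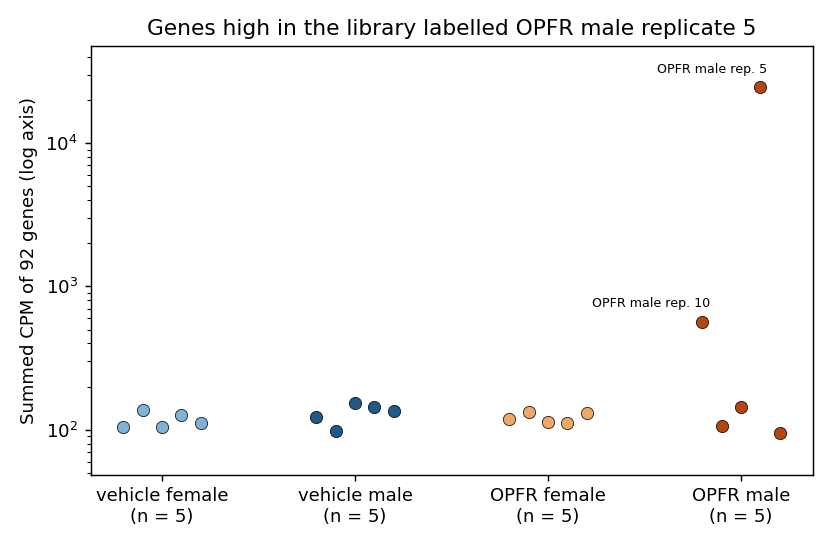
Summed CPM, on a log axis, of the 92 genes high in the library labelled OPFR male replicate 5, with 1 point per library in each of the 4 groups of 5. That library lies at 24400 CPM and OPFR male replicate 10 at 566, and the other 18 libraries lie between 94.7 and 153.

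Female and male placentas were compared over both treatments. edgeR called 6 genes, all higher in the libraries labelled male, with log2 fold changes (female over male) between -8.12 and -5.58 and adjusted p up to 0.00177. ENSRNOG00000057231 averaged 0.166 ± 0.21 CPM in labelled females and 52.2 ± 19.9 CPM in labelled males (SD, n = 10 each), a log2 fold change of -8.12 ± 0.76 (SE) with an adjusted p of 7.89e-06. ENSRNOG00000060048 averaged 0.438 ± 0.45 against 101 ± 37.4 CPM, a log2 fold change of -7.78 ± 0.76 with an adjusted p of 1.29e-05. The 10 libraries labelled female summed to 0.353 to 3.21 CPM over the 6 genes. Of the 10 libraries labelled male, 9 summed to 197 to 246 CPM, and the library labelled OPFR male replicate 7 summed to 0.297 CPM, with 10 reads where 7400 would be met at the mean level of the other 9.

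**Figure D5:**
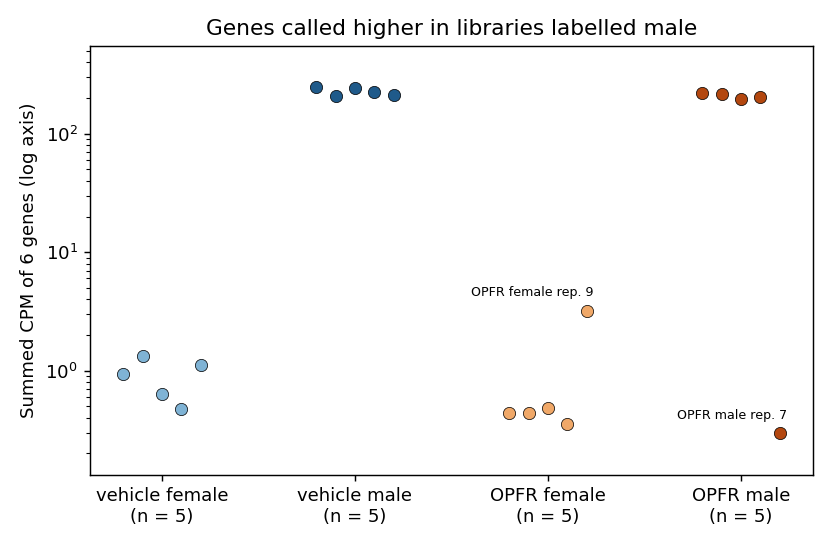
Summed CPM, on a log axis, of the 6 genes called higher in libraries labelled male, with 1 point per library in each of the 4 groups of 5. The library labelled OPFR male replicate 7 lies at 0.297 CPM, below the lowest labelled female library at 0.353, and the other 9 labelled males lie between 197 and 246.

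The count for sex depended on that library and on the test. Without OPFR male replicate 7, edgeR called 10 genes, 3 higher and 7 lower in females, and with it entered as female, 12 genes, 5 higher and 7 lower, which included all 6 of the genes called with the deposited labels. DESeq2 called 11 genes with the deposited labels, 3 higher and 8 lower in females, and limma-voom 2, both higher in females, so that none of the 6 was among them. At an unadjusted p under 0.05 there were 421 genes in edgeR, and 655 without vehicle female replicate 2. Every direction given for males or for the interaction rests on the label of OPFR male replicate 7 as deposited. Without it, edgeR called 0 genes in males and 0 for the interaction, with 1423 and 206 at an unadjusted p under 0.05. With it entered as female, those counts were 1470 in males, 254 for the interaction and 477 in females, with 0 called in each.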

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

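The tests of a wrong label and of a swap were chosen only after the result was seen, and the test of another tissue was not. In 56 comparisons of a library with the 4 others of its group, over 14 measures, 9 values stood far from the rest, where chance would give 2.8 if the measures were independent. They came from 5 libraries, and 6 of the 9 are the male-high sum and its 2 printed members in 2 of these libraries, which are not independent.

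The library labelled OPFR male replicate 7 stood apart from the other 4 OPFR males in the sum of the 6 male-high genes, at 0.297 CPM against 197 to 221, and in both printed members of that set. ENSRNOG00000057231 lay at 0.0297 CPM in it against 45.2 to 53.2 in the others, and ENSRNOG00000060048 at 0.0892 CPM against 97.5 to 121. A swap with a library labelled female is argued against, since 0 of the 10 reached the lowest of the other labelled males. The median correlation of OPFR male replicate 7 with the other 19 libraries was 0.973, within their range of 0.953 to 0.98. No library of another tissue gives a reference for that value. It therefore cannot decide whether another tissue took the place of the placental punch. A single wrong sex label, or a sample of another fetus, may account for the low male-high sum of this library. Of the 3 genes called higher in females without it, 3 lay nearer the female than the male mean in it (2 within the female range). A loss of the male-high genes alone would not give this. That 6 of the 7 genes called higher in males also lay nearer the female mean largely restates the low sum and adds no support. Few genes carry the test on female-high genes. The other 9 labelled males were placed by genes called without each in turn, with OPFR male replicate 7 entered as female. That placement takes the wrong label as given. Of these males, vehicle male replicates 5 and 3 had 3 of 6 and 1 of 4 female-high genes nearer the female mean. No biological explanation was tested.

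OPFR female replicate 9 had a male-high sum of 3.21 CPM against 0.353 to 0.488 in the other 4 OPFR females, with ENSRNOG00000057231 at 0.71 CPM and ENSRNOG00000060048 at 1.66 CPM. OPFR female replicate 8 had 67125069 counts against 23268010 to 35036880 in the others of its group. The TMM factor of OPFR male replicate 4 was 0.84 against 1.047 to 1.1. It was not alone at a low factor: vehicle male replicates 5 and 9 had 0.739 and 0.845, against 0.997 to 1.081 in the others of their group. On the second principal component, vehicle female replicate 2 lay at 33.04 and the other 4 vehicle females between -26.46 and -16.21.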

How the results depend on the processing

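4 alternatives were chosen only after the results were seen: the 3 that omit or re-enter the libraries labelled OPFR male replicates 5 and 7, and the 3 surrogate variables. For the numbers of called genes in the order both sexes, females, males and female against male, DESeq2 gave 187, 1, 8 and 11 in place of 0, 0, 0 and 6, and DESeq2 omitting OPFR male replicates 5 and 7 gave 131, 1, 3 and 17, with 100 of the 131 also among the 187. For female against male, limma with voom gave 2, with or without correlated label numbers, both higher in females and so none of the 6, and OPFR male replicate 7 entered as female gave 12. With 3 surrogate variables, the number that sva estimated from these data, 45 genes were called over both sexes and 1 in males. Leaving out 1 library in turn gave 0 to 27 genes over both sexes (27 without vehicle male replicate 3), 0 to 1 in females (without OPFR female replicate 9), 0 to 1 in males (without vehicle male replicate 9), 0 to 0 for the interaction and 6 to 10 for female against male (10 without OPFR male replicate 7). The cause was not tested. Each other alternative gave 0 for those of the treatment and interaction results it was run on, and within 1.5 times of 6 for sex where run. Counts summed by label number were run over both sexes alone (0), and the label number as a block for sex alone (6).

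With the replicate block, 0 genes were called for treatment and the interaction and 5 for sex. Same-numbered libraries of the 2 treatments did not deviate together (10 pairs, correlations from -0.49 to 0.33, 3 above 0.1). Of these libraries, 0 OPFR and 2 vehicle libraries correlated best with their own number. No pairing of the 2 treatments by number was therefore seen, though most pairs join opposite sexes. Within a treatment the replicate number runs with the label number. The 4 IDs printed for treatment kept their direction in the 36 alternatives, with adjusted p from 1.65e-06 to 0.739. All 4 passed the threshold with DESeq2 and without vehicle male replicate 3. The 2 male-high IDs also kept theirs, and lost significance with limma-voom (adjusted p up to 1), as 1 did with the replicate block (0.0575). Scaling moved the median log2 fold change of all genes between 0 and 0.005. Gene list tests and tissue covariates were not run, as the files used did not pair the IDs with names, and the pseudocount was not needed for counts. At these depths and group sizes, with libraries simulated as independent, 10% of genes simulated at 1.25-fold were recovered over both sexes and 10% of those at 1.5-fold for the interaction. Depth was not varied apart from the number of libraries.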

Other observations

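The test between label numbers, the tests on ENSRNOG00000014171, and 2 of the 3 tests on OPFR male replicate 5 (response to OPFR and carry-over) were chosen only after the results were seen. The comparisons with other splits of the samples were otherwise set before those splits were run. The permutation test of the principal components by label number was not among them.

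Other splits of the same libraries show how far chance can be excluded. Each set of splits below includes the labelled split, which is counted among those that gave as many. For 1866 genes at an unadjusted p under 0.05 over both sexes, 15 of 100 splits of treatment within sex gave as many (highest other 4680), and so did 17 of 100 drawn from the 126 splits of whole label numbers (highest other 5021, with 10 to 12 libraries on the OPFR side), so chance is not excluded. For the 187 genes called by DESeq2 it was 8 of 100 splits (highest other 3050), and 34 of the 100 called at least 1 gene. For 591 genes in females it was 21 of 65 splits (highest other 2553), for 1233 in males 21 of 71 (highest other 4097), and for 190 in the interaction 95 of 100 (highest other 5052). The correlation of 0.304 between the female and male fold changes was matched in 11 of 100 splits within sex (highest other 0.489) and in 16 of 100 splits of whole label numbers (highest other 0.479). Chance is excluded at the 0.05 level for the 6 genes of female against male, with 2 of 100 splits (highest other 341). Some splits called far more genes than the labelled one: edgeR called up to 2362 genes for treatment permuted within sex and up to 3155 for whole label numbers, which points to a structure of the samples other than treatment and sex.

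That structure was compared with the label number. With treatment and sex held, edgeR called 75 genes between the 9 numbers (7 degrees of freedom). Of 100 arrangements of the numbers within treatment, the labelled one included, 2 gave as many (highest other 1294). This test was chosen after the results were seen, so that share cannot exclude chance at the 0.05 level. On the second principal component 77.9% of the variance within treatment lay between numbers (permutation test with 100000 resamples, p = 0.00885, adjusted over 5 components 0.0442). The first component, with 35.7% of the variance, did not show this (21.5% between numbers, p = 0.861), and components 3 to 5 gave p of 0.231, 0.613 and 0.144 in the same permutation test. OPFR replicates 1 and 2 lay at 22.3 and 26.5, replicates 5 and 6 at 3.5 and 42.4, and replicates 9 and 10 at 10.2 and 35.5, whereas replicates 3 and 4 lay at -12.5 and -11.6 and replicates 7 and 8 at -17.7 and -17.3 (lower value first). Of the vehicle libraries, replicates 1 and 2 lay at 12.8 and 33.0, replicates 3 and 4 at -20.0 and -18.4, replicates 5 to 8 between -23.5 and 3.5, and replicates 9 and 10 at -26.5 and -16.3. On the first component, vehicle male replicate 5, OPFR male replicate 4 and vehicle male replicate 9 lay at -79.91, -45.25 and -36.37. They had the lowest TMM factors (0.739, 0.84 and 0.845). Their 10 most abundant genes held the highest shares of reads (17.52%, 12.48% and 13.99%). Vehicle female replicate 2 lay at -41.4 with a factor of 0.956 and a share of 7.58%. Whether this component follows the makeup of the libraries was not tested.

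ENSRNOG00000014171, the printed gene with the smallest p for treatment, is 1 of the 75. OPFR treatment alone is argued against, since 3 vehicle libraries lay within the OPFR range of 1.86 to 4.2 CPM and a 4th at 4.38. Its adjusted p between numbers within treatment was 0.00259 in edgeR, but this restates the split by number already seen in its values and adds no support for a factor shared by libraries of a number, which stays open. The labels do not say what the number marks. ENSRNOG00000020683, ENSRNOG00000014530 and ENSRNOG00000002899 had adjusted p of 0.94, 0.942 and 0.355 in that test.

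The genes high in the library labelled OPFR male replicate 5 were weighed too. The 92 genes were chosen as low elsewhere, so 2 tests used the 146 genes at 5 CPM or more and over 10 times the median of the other 19 libraries, which leaves other libraries free to hold as much. These summed to 25729 CPM in it. Of the other 4 OPFR males, 3 lay within or below the vehicle male range of 373 to 546 CPM. OPFR male replicate 7 lay below it at 173 CPM, as the labelled females did at 176 to 219 CPM. The set was not cleared of male-high genes, so replicate 7 does not bear on the question. A response to OPFR of that size shared by its group is argued against by OPFR male replicates 2 and 4, within the range at 394 and 421 CPM. The 6 male-high genes summed to 218 and 197 CPM in these 2 libraries and to 208 to 246 CPM in vehicle males. These genes could therefore hide a smaller shared rise, which is not excluded. Carry-over from another of the 20 libraries is argued against, since the highest sum elsewhere was 926 CPM. A single source of RNA that is also present at a low level in OPFR male replicate 10 is consistent with a rank correlation of 0.88 across the 92 genes between the 2 libraries, against at most 0.7 for the other 18. Carry-over from replicate 5 into replicate 10 predicts the same and was not tested, and without gene names the source stays unnamed.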
